A study of Mus musculus with 60 samples.

How the data were processed

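The data were 60 two-colour oligonucleotide arrays of RNA from primary mouse hepatocytes. There were 2 genotypes (WT, Cre control; KO, Alb-Cre with both Met alleles floxed) and 5 times (untreated, and 0.5, 2, 12 and 24 h of HGF), with 3 replicates in each of the 10 groups. Replicates in a group were labelled separate mice, which times may share. Each replicate was read on 2 dye-swapped arrays against pooled WT hepatocyte RNA. The deposited values are normalized log2 ratios, 1 per probe and array. The log base was inferred from the range (largest absolute value 11.6), and the normalization method is not given in the sources used here. Which sample is the numerator is not stated either. Dye pairs were assumed, without a test, to be already turned to sample over reference.

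Several labels conflict. The treatment field gives 0.5 h for the 12 h samples, and the titles were used. The dose is given both as 50 ng/ml and as 50 nM. The strain label differs with the genotype on all arrays, so strain and genotype changed together. Array numbers fall into 4 sets (A, 4 arrays; B, 7; C, 27; D, 22). All 0.5 h replicates and all 2 h replicates but KO replicate 3 lie in set D, all 12 h replicates in set C, and the untreated and 24 h replicates in sets A, B and C. The Cy3 array of WT 24 h replicate 2 lies in set B and its Cy5 array in set C, and it was counted in set C. The 2 early times are thus linked to untreated only through set A, and time and array set are otherwise confounded there.

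Array medians were -0.154 to 0.144, SD 0.287 to 1.39, and 6.01% of values were missing. Of 30 dye pairs, 23 had negative r as deposited (-0.677 to 0.186 over probes). Then 3 profiles of the orientation difference (58.7, 9.51 and 7.05% of its variance) and probe means per dye were regressed out. That itself raises r and left all 30 positive (lowest 0.0559, median 0.288). The Cy5 array of WT 0 h replicate 3 was in all 19 pairs of arrays of 1 dye with r under -0.3, so its direction is unsettled and was turned in an alternative. WT 0 h replicate 3 and the noisy KO 24 h replicate 2 are called the doubted replicates.

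Each array was centred on its median and the 2 orientations were averaged to 1 value per replicate. Of 21997 probes, 16076 were annotated with 1 gene symbol (15877 updated through the gene table, 199 kept as annotated), 288 with several and 5633 with none. A probe was tested if at least 2 of 3 replicates in all 10 groups had both orientations, which left 14580 probes (66.3%), 10963 of them with 1 symbol, for 10074 genes. The choices of filter, fit, comparisons, gene lists and named genes were made before the data were examined, except the 4 alternatives named last. Which of the named genes are printed was decided after their values were seen.

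limma 3.58.1 in R 4.3.3 fitted 1 mean per group to all 30 replicates, with 20 residual and 4.48 prior degrees of freedom. Compared were KO and WT at each time, and each HGF time and untreated per genotype. The difference of these responses was tested at each and any time (moderated F-test). KO against WT averaged over time had genotype by repeat number as a random block (statmod 1.5.0, correlation -0.0023, so little changed). Tests were two-sided, with probes called at a Benjamini-Hochberg adjusted p under 0.05. Elsewhere times were not paired, as 10 of 30 replicates correlated best with their own number, which cannot show independence. The 31 gene lists were tested with camera at a preset correlation of 0.01 and adjusted over the lists of a comparison, each gene read from the probe with values on most arrays, with 2.30% of values imputed by the group mean. The lists include markers of other liver cell types and housekeeping genes.

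Named genes are probes with 1 symbol. Untreated and averaged these are the 8 highest and 8 lowest called, for HGF in WT 5 and 5. For HGF in KO and KO against WT at HGF times it is 3 and 3, for differences 4 and 4. Replicates must not overlap, but averaged only the sign at the 5 times must agree. Further named are up to 4 members of a called list and 2 of any other list, and the panel Met, Fos, Egr1, Myc, Ccnd1 and Alb. The probes of Myc and Ccnd1 failed the probe filter.

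The method was tested on 14580 simulated probes, each with 1 spread in all groups. For HGF 24 h in WT, 12 of 67 changes of log2 0.5 were called, 57 of 67 of 1 and 63 of 66 of 2, with 7 calls among 14380 unchanged probes. For the difference at 24 h the shares were 4.48, 37.3 and 92.4%, with 4 false calls. With no change anywhere and each group's own spread, 10 simulations were fitted. KO against WT at 24 h then had a median of 311 calls in the fit with 1 shared spread and 0 with weights.

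Alternatives changed 1 choice at a time: no centring, scale normalization, 1 orientation being enough, single arrays with a dye term, stricter and looser probe filters, only the groups compared, a replicate block, array set as a term, leaving out array sets A and B, 1 dye only, leaving out each replicate, and for gene lists an estimated correlation and the mean over probes. Added after seeing the data were removal of the 3 dye profiles, the turned sign, leaving out both doubted replicates, and replicates weighted by the spread of their group (limma's arrayWeights). Figures were drawn with python 3.11.15 and matplotlib 3.10.9. Time-matched untreated cultures were not analysed here.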

Results

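Primary mouse hepatocytes carrying Alb-Cre with a deleted Met gene (KO) were compared with Cre control hepatocytes (WT). Met is the receptor of hepatocyte growth factor (HGF), and Alb-Cre deletes it in hepatocytes. RNA was taken before treatment and 0.5, 2, 12 and 24 h after HGF was added, which gave 10 groups of 3 replicates. Each replicate was read on 2 two-colour oligonucleotide arrays with exchanged dyes against pooled WT hepatocyte RNA, 60 arrays in all. Arrays held values for 17356 to 21511 of 21997 probes, and 14580 probes were tested. For arrays, the number of replicates limits the precision. Values are log2 differences ± the standard error from limma. Replicates were 3 and 3 where no n is given, and other numbers follow the order of the comparison. No untreated cultures of the later times were analysed here, so time in culture and HGF changed together in each comparison over time. Groups differed in spread, with residual SD from 0.165 (WT 2 h) to 0.431 (KO 24 h), so counts are also given with replicates weighted by the spread of their group. The direction of the Cy5 array of WT 0 h replicate 3 is unsettled, and counts are also given with its sign turned. Across probes the differences on Cy5 and on Cy3 arrays correlated at r = -0.449 to 0.326 over the comparisons.

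Met was measured by 1 tested probe, whose position relative to the deleted exons is not known. Its mean log2 ratio ± SD in WT was 0.23 ± 0.05 (n = 2) untreated, 0.29 ± 0.10 at 0.5 h, -0.06 ± 0.10 at 2 h, 0.45 ± 0.11 at 12 h and -0.09 ± 0.65 (n = 2) at 24 h. In KO it was 0.20 ± 0.21, 0.28 ± 0.12, 0.09 ± 0.18, 0.42 ± 0.02 (n = 2) and 0.21 ± 0.22 at the same times. None of the 5 genotype differences passed the test, so this probe did not show the deletion. Alb, the major secreted protein of hepatocytes, did not pass between the genotypes at any time (-0.11 to 0.11). Egr1, a growth factor induced transcription factor, changed in WT by 0.72 ± 0.27 at 0.5 h (adjusted p = 0.233), which did not pass. The HGF-MET axis list, with 14 measured members, passed in none of the 18 list comparisons, and neither did apoptosis regulators, TGF-beta and BMP targets, or the marker lists of stellate cells, lymphocytes and red blood cells. Lists were tested with camera at a preset correlation against all other genes, so a list called shifted or higher moved relative to them, whether or not any member passed. Of 131 list calls, 10 also passed with an estimated correlation: amino acid and urea metabolism in WT at 12 h and in KO at 12 and 24 h, P450 genes in WT at 12 and 24 h, hepatocyte secreted and differentiation genes in WT at 24 h, and 4 lists in the genotype difference averaged over time.

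Untreated KO and WT hepatocytes were compared to ask what differed between the genotypes before HGF was added. Met differed by -0.03 ± 0.19 (n = 3 and 2). The uncharacterised gene 1700001D01Rik was 5.78-fold higher in KO (2.53 ± 0.24, n = 2 and 3), and Prelid2, coding for a mitochondrial protein, was 3.72-fold higher (1.89 ± 0.25). Also higher in KO were Aldh1a1 (1.33 ± 0.24) and Aldh1a7 (0.99 ± 0.17), aldehyde dehydrogenases of which the former makes retinoic acid, and Ankrd1, a target of YAP signalling (1.65 ± 0.28). Mmp7, a secreted metalloprotease, was lower (-1.33 ± 0.26, n = 2 and 3). Of amino acid and urea metabolism genes, 0 of 18 measured members were higher, 0 lower and 18 did not pass (3 and 0 adjusted over the list alone, adjusted p = 1.41e-05), and Ass1, the urea cycle enzyme argininosuccinate synthase, differed by 0.66 ± 0.14 without passing. Of unfolded protein and amino acid stress genes, 0 of 23 measured members were higher, 0 lower and 23 did not pass (0 and 8 adjusted over the list alone, adjusted p = 2.43e-07), with the chaperone partner Creld2 at -0.998 ± 0.23. Cytoskeleton and motility genes and oxidative stress and glutathione genes were higher as lists (adjusted p = 1.41e-05 to 0.00574, 0 members called in each, 0 to 2 adjusted over the list alone). These 4 lists had an adjusted p = 0.235 to 0.724 with an estimated correlation. limma called 9 of 14580 probes, 6 higher and 3 lower in KO, and 18 (10 and 8) with dye profiles removed. Scale normalization gave 15 (6 higher and 9 lower), no centring 7 (6 and 1), and the turned sign 12 (6 and 6). A fit of only the compared groups gave 0 (463 probes at an unadjusted p under 0.05). With weights 2 calls were left, both shared, 1700001D01Rik and Prelid2, but the first was -0.07 on the Cy3 arrays alone, and the turned sign ended the call of the second. Leaving out KO replicate 1 or 2 or WT replicate 2 ended the calls of Aldh1a1, Aldh1a7, Ankrd1 and Mmp7. Those of Aldh1a1, Aldh1a7 and Mmp7 were also lost without WT replicate 1 or KO replicate 3, and scale normalization ended those of Aldh1a1 and Aldh1a7 and the turned sign that of Mmp7. The count was 2 without KO replicate 1 or KO replicate 2 or WT replicate 2, 45 without WT replicate 3, and 73 within array set C, the run of array numbers that holds most untreated and later replicates.

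After 0.5 h of HGF the genotype comparison asked how KO and WT hepatocytes differed early in the response. Met differed by -0.01 ± 0.17. Hbegf, a growth factor of the EGF receptor, was 2.54-fold lower in KO (-1.34 ± 0.15, adjusted p = 3.52e-05), and Tuba1a, an alpha-tubulin, was 2.78-fold lower (-1.47 ± 0.27). Hamp, the iron regulator hepcidin, was 6.08-fold higher (2.60 ± 0.41), as were Prelid2 (1.95 ± 0.25) and the lipogenic enzyme Fasn (1.44 ± 0.38). The vesicle protein Vamp1 was also lower (-2.24 ± 0.34). Of amino acid genes, 3 of 18 measured members were higher, 1 lower and 14 did not pass (4 and 1 adjusted over the list alone, adjusted p = 9.60e-05). Of unfolded protein genes, 0 of 23 measured members were higher, 4 lower and 19 did not pass (0 and 12 adjusted over the list alone, adjusted p = 9.60e-05). Called members included the disulfide isomerases Pdia6 (-1.44 ± 0.26) and Pdia4 (-1.82 ± 0.47). Neither list passed with an estimated correlation (adjusted p = 0.372 and adjusted p = 0.693). Among markers of other cell types, Dcn of stellate cells (-1.13 ± 0.22) and Cftr of bile duct cells (-1.17 ± 0.27) were lower. The calls of Fasn and Pdia4 were lost without any 1 replicate, and that of Cftr without WT replicate 1 or KO replicate 2 or 3. limma called 627 probes, 291 higher and 336 lower, against 3064 (1339 and 1725) with weights and 384 with dye profiles removed, of which 263 were shared. The Cy5 arrays alone called 58 and the Cy3 arrays alone 1741, the differences on the 2 correlated at r = 0.0145, and the dye profiles had a squared correlation of 0.411 with the comparison. All 12 arrays lay in array set D, but the arrays of each genotype formed a separate run of numbers. With 2 replicates in a group fewer probes passed, 151 without KO replicate 2, 211 without WT replicate 3, 284 without WT replicate 2, 302 without KO replicate 1, 303 without KO replicate 3, 373 without WT replicate 1, the turned sign gave 732 and a fit of only the compared groups 2256.

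At 2 h the comparison asked the same question of the next step of the response. Met differed by 0.15 ± 0.17. Capn11, a calcium-dependent protease, was 9.96-fold higher in KO (3.32 ± 0.31, adjusted p = 4.91e-06), and Cyp2a4, a steroid hydroxylase, was 8.87-fold higher (3.15 ± 0.35). Nat8f5, an acetyltransferase family member, was higher by 1.60 ± 0.24. Junb, an immediate early transcription factor, was lower (-0.94 ± 0.21, adjusted p = 0.0437), a call lost without WT replicate 2 or 3 or KO replicate 2 or 3. Slc7a11, the cystine importer, was also lower (-1.32 ± 0.29), a call lost without any 1 replicate. Among P450 and phase II genes, 2 of 33 measured members were higher, 0 lower and 31 did not pass (6 and 0 adjusted over the list alone, adjusted p = 1.94e-06). Of fatty acid oxidation genes, 2 of 21 measured members were higher, 0 lower and 19 did not pass (4 and 0 adjusted over the list alone, adjusted p = 3.18e-05). In the glutathione list, 3 of 39 measured members were higher, 1 lower and 35 did not pass (3 and 1 adjusted over the list alone, adjusted p = 0.00791). Of immediate early genes, 0 of 24 measured members were higher, 1 lower and 23 did not pass (0 and 2 adjusted over the list alone, adjusted p = 5.91e-04), and Egr1 was -1.08 ± 0.27 without passing (adjusted p = 0.0659). Bile acid, gluconeogenesis, acute phase and pericellular proteolysis genes were higher as lists (adjusted p = 8.56e-04 to 0.0140, 0 to 2 members called in each, 0 to 4 adjusted over the list alone), and ribosome biogenesis genes lower (0 up and 0 down of 20, 0 and 1 adjusted over the list alone, adjusted p = 0.0119). Kupffer cell markers were also higher as a list (0 up and 0 down of 11, 2 and 0 adjusted over the list alone, adjusted p = 0.0275), with Marco at 0.49 ± 0.15. Under an estimated correlation these 10 lists had adjusted p = 0.262 to 0.703. limma called 63 probes, 46 higher and 17 lower, all shared with the 167 called after removal of dye profiles, and 615 (428 and 187) with weights. The count was 25 without KO replicate 2, 26 without WT replicate 2, 29 without WT replicate 3, 35 without WT replicate 1, 40 without KO replicate 3, 46 with the sign turned, 192 within array set D alone, where KO has 2 replicates, 1046 after scale normalization and 402 in a fit of only the compared groups.

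At 12 h, when KO and WT arrays all lay in array set C, the genotypes were compared during the late response. Met differed by -0.03 ± 0.19 (n = 2 and 3). Aldh1a1 was 5.85-fold higher in KO (2.55 ± 0.24, adjusted p = 1.06e-06) and Adh1, an alcohol dehydrogenase of retinol and ethanol metabolism, 3.76-fold (1.91 ± 0.26). In the P450 list, 8 of 33 measured members were higher, 0 lower and 25 did not pass (15 and 0 adjusted over the list alone, adjusted p = 7.87e-14). Of glutathione genes, 10 of 39 measured members were higher, 2 lower and 27 did not pass (15 and 2 adjusted over the list alone, adjusted p = 1.99e-10). Of fatty acid and triglyceride synthesis genes, 3 of 22 measured members were higher, 0 lower and 19 did not pass (5 and 0 adjusted over the list alone, adjusted p = 7.37e-04), with Gpam, which starts triglyceride synthesis, at 0.87 ± 0.14 and Scd1, a fatty acid desaturase, at 1.32 ± 0.30, a call lost without WT replicate 2 or KO replicate 1 or 3. Of unfolded protein genes, 0 of 23 measured members were higher, 3 lower and 20 did not pass (0 and 7 adjusted over the list alone, adjusted p = 3.35e-04), with Creld2 (-1.67 ± 0.23) and Pdia6 (-1.27 ± 0.26) lower. Fatty acid oxidation, amino acid, hepatocyte and gluconeogenesis genes were higher as lists (adjusted p = 2.69e-07 to 0.0381, 1 to 4 members called in each, 1 to 11 adjusted over the list alone), and ribosome biogenesis genes lower (adjusted p = 0.0300, 0 members called). None of the 9 lists passed with an estimated correlation (adjusted p = 0.0562 to 0.790). Dnase1l3, a marker of liver endothelial cells, was lower in KO (-1.32 ± 0.23). limma called 414 probes, 188 higher and 226 lower, 813 (366 and 447) with weights and 628 with dye profiles removed, of which 391 were shared. Arrays of each genotype formed a separate run of numbers. The count was 213 without WT replicate 2, 228 without WT replicate 1, 271 without KO replicate 3, 272 without KO replicate 1, 459 with the sign turned and 234 after scale normalization.

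At 24 h the same comparison covered the latest time. Met differed by 0.30 ± 0.19 (n = 3 and 2). Gsta3 was 4.54-fold higher in KO (2.18 ± 0.12, adjusted p = 6.60e-12), Adh1 7.20-fold (2.85 ± 0.26), Aldh1a1 6.14-fold (2.62 ± 0.24) and Cyp2a5, a coumarin hydroxylase, 5.85-fold (2.55 ± 0.26). Enpp3, a membrane nucleotide pyrophosphatase, was 8.66-fold lower (-3.11 ± 0.47), the water channel Aqp1 7.78-fold lower (-2.96 ± 0.61) and the beta-tubulin Tubb6 4.24-fold lower (-2.08 ± 0.38). All 7 kept their calls with weights. In the glutathione list, 15 of 39 measured members were higher, 1 lower and 23 did not pass (15 and 2 adjusted over the list alone, adjusted p = 5.19e-11). Of fatty acid oxidation genes, 8 of 21 measured members were higher, 0 lower and 13 did not pass (11 and 0 adjusted over the list alone, adjusted p = 2.96e-07). Of P450 genes, 8 of 33 measured members were higher, 0 lower and 25 did not pass (13 and 1 adjusted over the list alone, adjusted p = 2.50e-08). Of hepatocyte genes, 6 of 38 measured members were higher, 0 lower and 32 did not pass (7 and 0 adjusted over the list alone, adjusted p = 4.25e-04). Of cytoskeleton, adhesion and motility genes, 1 of 41 measured members were higher, 8 lower and 32 did not pass (2 and 9 adjusted over the list alone, adjusted p = 0.0429). Bile acid and acute phase genes were higher as lists (adjusted p = 0.0141 to 0.0477, 1 to 3 members called in each, 2 to 5 adjusted over the list alone) and cell cycle genes lower (0 up and 2 down of 25, 0 and 2 adjusted over the list alone, adjusted p = 0.0477), although weighting ended the calls of Mcm5 (-0.61 ± 0.15) and Cdk4 (-0.87 ± 0.25), calls lost after scale normalization and without WT replicate 1 or 2 or KO replicate 2, and for Cdk4 KO replicate 3. Bile duct markers were lower as a list (1 up and 3 down of 10, 1 and 6 adjusted over the list alone, adjusted p = 0.0482), and the Kupffer cell marker Mpeg1 was higher (1.23 ± 0.23), a call that weighting ended. With an estimated correlation the 9 lists had adjusted p = 0.0926 to 0.791. limma called 695 probes, 351 higher and 344 lower, but simulations of 14580 probes with no change and these spreads gave a median of 311 calls (236 to 389), and with weights 127 (66 and 61) were called, against at most 1 in simulation. With dye profiles removed 876 (526 and 350) passed, 593 of them shared. Scale normalization gave 398 and a fit of only the compared groups 10. Array set B held 1 replicate of each genotype and the Cy3 array of WT replicate 2, which was counted in set C by its Cy5 array. The count was 1562 (487 higher and 1075 lower) without set B so defined, 1344 without WT replicate 3 (427 and 917) and 697 with the sign turned.

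Averaged over the 5 times, the comparison asked what differed between the genotypes whatever the time. Met differed by 0.08 ± 0.08 and was not called. Aldh1a7 (1.43 ± 0.08, adjusted p = 7.13e-12) and Aldh1a1 (1.84 ± 0.11) were 2.70-fold and 3.59-fold higher in KO, and Pik3r1, the regulatory subunit of phosphoinositide 3-kinase that receptors such as Met bind, was 2.06-fold higher (1.04 ± 0.10). Immediate early genes Junb (-0.77 ± 0.10) and Egr1 (-0.57 ± 0.12, adjusted p = 0.00211) and the growth factor Hbegf (-0.56 ± 0.07) were lower in KO. Of glutathione genes, 16 of 39 measured members were higher, 2 lower and 21 did not pass (19 and 2 adjusted over the list alone, adjusted p = 1.92e-10). Among P450 genes, 15 of 33 measured members were higher, 0 lower and 18 did not pass (18 and 0 adjusted over the list alone, adjusted p = 2.23e-13), and of fatty acid oxidation genes, 12 of 21 measured members were higher, 1 lower and 8 did not pass (13 and 1 adjusted over the list alone, adjusted p = 4.03e-08). Of amino acid genes, 9 of 18 measured members were higher, 1 lower and 8 did not pass (10 and 1 adjusted over the list alone, adjusted p = 1.88e-06). These 4 lists also passed with an estimated correlation (adjusted p = 0.0385 for each). Of fatty acid and triglyceride synthesis genes, 5 of 22 measured members were higher, 0 lower and 17 did not pass (7 and 1 adjusted over the list alone, adjusted p = 0.00225). Of unfolded protein genes, 0 of 23 measured members were higher, 10 lower and 13 did not pass (1 and 11 adjusted over the list alone, adjusted p = 8.91e-06). Cell cycle genes were lower as a list (0 up and 3 down of 25, 0 and 3 adjusted over the list alone, adjusted p = 0.0480). Ribosome biogenesis genes were also lower (1 up and 1 down of 20, 1 and 8 adjusted over the list alone, adjusted p = 0.0271), and gluconeogenesis and bile acid genes higher (adjusted p = 0.0403, 3 to 8 members called in each, 3 to 9 adjusted over the list alone). The last 6 lists had adjusted p = 0.0742 to 0.702 with an estimated correlation. Endothelial markers Dnase1l3 (-0.48 ± 0.10) and Clec4g (-0.32 ± 0.09) were lower in KO, while Krt23 of bile duct cells (0.54 ± 0.06) and Mpeg1 of Kupffer cells (0.36 ± 0.10) were higher, the latter not with array set as a term or without sets A and B. limma called 1488 probes, 737 higher and 751 lower, 1373 with weights (1277 shared), 1816 (1037 and 779) with dye profiles removed (1348 shared), and 1962 (816 and 1146) with the sign turned. Leaving out 1 replicate gave 1229 to 2074, and the genotypes also differed in their strain label.

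**Figure D1:**
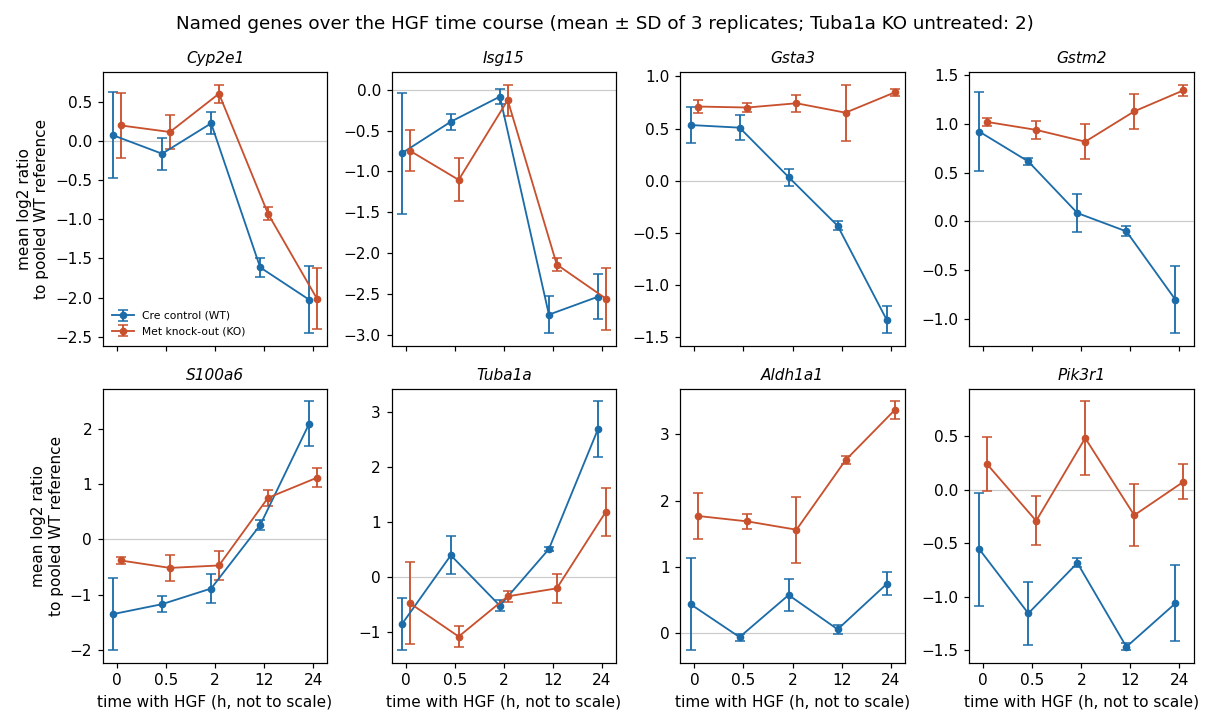
Mean log2 ratio to pooled WT RNA ± SD of the replicates (3 per group, 2 for Tuba1a in untreated KO) of 8 genes against hours of HGF, with WT and KO as separate lines. Gsta3 and Gstm2 fell in WT at 12 and 24 h and were higher in KO at both times, while Tuba1a and S100a6 rose in both genotypes by 24 h.

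In WT, the comparison of 0.5 h of HGF with untreated asked which genes responded first. Met was 0.06 ± 0.19 (n = 3 and 2) from untreated. Hbegf rose 2.37-fold (1.25 ± 0.15, adjusted p = 4.03e-04), and Vamp1 rose by 2.16 ± 0.34 and the nucleoside transporter Slc29a1 by 1.29 ± 0.21. Weighting ended the call of Vamp1, and leaving out untreated replicate 3, the turned sign and removal of dye profiles that of Slc29a1. Of ERK pathway feedback regulators, 1 of 16 measured members rose, 0 fell and 15 did not pass (4 and 0 adjusted over the list alone, adjusted p = 0.0258), with the EGF receptor inhibitor Errfi1 at 1.29 ± 0.45. Of cytoskeleton genes, 0 of 41 measured members rose, 0 fell and 41 did not pass (3 and 0 adjusted over the list alone, adjusted p = 0.00160), with Tuba1a at 1.25 ± 0.27 (adjusted p = 0.0606) and Actg1, an actin, at 0.86 ± 0.22 (0.16 by its other probe), both without a call. Ribosome biogenesis, chemokine and housekeeping genes were also shifted up as lists (adjusted p = 0.00733 to 0.0199, 0 members called in each, 0 to 1 adjusted over the list alone). Under an estimated correlation all 5 had adjusted p = 0.763. The immediate early gene Fos was -0.22 ± 0.17 without passing. limma called 18 probes, 16 up and 2 down, 7 with weights and 8 with dye profiles removed (7 shared), 152 (114 up and 38 down) after scale normalization and 3 with the sign turned. A fit of only the compared groups gave 0 (1605 probes at an unadjusted p under 0.05), which ended the call of Hbegf. Treated and untreated replicates lay in different array sets, and with array set as a term 2 calls were made, 0 of them shared. The count was 5 without untreated replicate 3, 8 without treated replicate 1 and 652 without untreated replicate 2.

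At 2 h in WT, Met was -0.28 ± 0.19 (n = 3 and 2) from untreated. Jun, an immediate early transcription factor, rose 1.93-fold (0.95 ± 0.20, adjusted p = 0.0277), a call that weighting ended, as did leaving out any 1 replicate but untreated replicate 3. Capn11 fell 11.1-fold (-3.47 ± 0.31) and Cyp2a4 fell 9.89-fold (-3.31 ± 0.35). The bile acid enzymes Cyp27a1 (-1.17 ± 0.17) and Baat (-1.07 ± 0.18) also fell. Of immediate early genes, 1 of 24 measured members rose, 0 fell and 23 did not pass (4 and 0 adjusted over the list alone, adjusted p = 0.00170). Of bile acid genes, 0 of 15 measured members rose, 2 fell and 13 did not pass (0 and 4 adjusted over the list alone, adjusted p = 0.00118). In the glutathione list, 0 of 39 measured members rose, 3 fell and 36 did not pass (0 and 7 adjusted over the list alone, adjusted p = 0.00598), with Gstm2 (-0.83 ± 0.16) and Gstm6 (-0.75 ± 0.14) lower, calls lost without untreated replicate 2 or treated replicate 1. Interferon response genes (0 up and 0 down of 29, 2 and 0 adjusted over the list alone, adjusted p = 2.45e-06) were shifted up as a list and unfolded protein genes down (0 up and 0 down of 23, 0 and 10 adjusted over the list alone, adjusted p = 4.61e-06). With an estimated correlation each of the 5 lists had adjusted p = 0.584. limma called 65 probes, 18 up and 47 down, 32 with weights, 245 with dye profiles removed (64 shared) and 1098 with the sign turned. Scale normalization gave 1343 (400 and 943), leaving out sets A and B 1568, and a fit of only the compared groups 1, which kept Capn11. With array set as a term 1 call was made, not among the 65, Jun moved to -0.22 and Baat to 0.17. The count was 20 without treated replicate 1, 22 without treated replicate 2, 25 without untreated replicate 2 and 437 without untreated replicate 3.

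At 12 h in WT, Met was 0.22 ± 0.19 (n = 3 and 2) from untreated. S100a6, a calcium-binding protein of motile cells, rose 3.05-fold (1.61 ± 0.23), Ccn2, a matrix protein and YAP target, rose 6.44-fold (2.69 ± 0.45), and the membrane-cytoskeleton proteins Msn (1.53 ± 0.16, adjusted p = 1.85e-05) and Anxa2 (1.498 ± 0.21) rose. The ethanol-inducible P450 Cyp2e1 fell 3.22-fold (-1.69 ± 0.24) and Isg15, an interferon-induced ubiquitin-like protein, fell 3.93-fold (-1.98 ± 0.25). Of cytoskeleton genes, 16 of 41 measured members rose, 0 fell and 25 did not pass (21 and 1 adjusted over the list alone, adjusted p = 1.60e-10). In the P450 list, 0 of 33 measured members rose, 18 fell and 15 did not pass (0 and 24 adjusted over the list alone, adjusted p = 6.09e-18). Of hepatocyte genes, 0 of 38 measured members rose, 16 fell and 22 did not pass (1 and 21 adjusted over the list alone, adjusted p = 3.67e-12). Of amino acid genes, 1 of 18 measured members rose, 8 fell and 9 did not pass (1 and 10 adjusted over the list alone, adjusted p = 2.77e-08). Of interferon response genes, 0 of 29 measured members rose, 12 fell and 17 did not pass (0 and 19 adjusted over the list alone, adjusted p = 1.77e-13). Bile acid, fatty acid oxidation, fatty acid synthesis, glutathione, acute phase and chemokine genes were shifted down as lists (adjusted p = 9.16e-07 to 0.0414, 1 to 7 members called in each, 1 to 13 adjusted over the list alone), and ribosome biogenesis and heat shock genes up (adjusted p = 5.40e-05 to 1.48e-04, 2 to 4 members called in each, 5 to 7 adjusted over the list alone). The P450 and amino acid lists also passed with an estimated correlation (adjusted p = 0.0286), and the other 11 had adjusted p = 0.0706 to 0.433. Markers of other cells also fell, Mpeg1 of Kupffer cells (-1.02 ± 0.23), Col3a1 of stellate cells (-0.80 ± 0.16, n = 3 and 2) and Emcn of endothelial cells (-1.63 ± 0.47), each without a call after scale normalization. That of Emcn was also lost without any 1 replicate but untreated replicate 1, and that of Col3a1 with dye profiles removed. limma called 847 probes, 387 up and 460 down, 643 with weights, 1486 (900 and 586) with dye profiles removed (827 shared), 845 (228 and 617) with the sign turned, 222 after scale normalization and 88 in a fit of only the compared groups. The balance of up and down depended on the dye, with 881 and 234 on the Cy5 arrays alone and 230 and 615 on the Cy3 arrays alone, whose differences correlated at r = -0.161. The count was 318 without treated replicate 2, 331 without untreated replicate 3, 417 without treated replicate 1, 508 without treated replicate 3, and 884 within array set C.

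At 24 h in WT, Met was -0.32 ± 0.21 (n = 2 and 2) from untreated. Tuba1a rose 11.6-fold (3.54 ± 0.27, adjusted p = 7.97e-09), S100a6 10.9-fold (3.44 ± 0.23) and Cdk4, a kinase of the G1 phase, 2.60-fold (1.38 ± 0.25). Asgr1, the hepatocyte asialoglycoprotein receptor, fell 4.85-fold (-2.28 ± 0.20), Gsta3 3.65-fold (-1.87 ± 0.12) and Cyp2e1 4.28-fold (-2.10 ± 0.24). Of hepatocyte genes, 0 of 38 measured members rose, 24 fell and 14 did not pass (1 and 28 adjusted over the list alone, adjusted p = 1.27e-18). Of P450 genes, 0 of 33 measured members rose, 21 fell and 12 did not pass (0 and 22 adjusted over the list alone, adjusted p = 1.04e-15). Of acute phase genes, 0 of 25 measured members rose, 14 fell and 11 did not pass (0 and 18 adjusted over the list alone, adjusted p = 3.27e-11). Of cytoskeleton genes, 12 of 41 measured members rose, 3 fell and 26 did not pass (15 and 3 adjusted over the list alone, adjusted p = 2.27e-07). Of glutathione genes, 3 of 39 measured members rose, 10 fell and 26 did not pass (4 and 12 adjusted over the list alone, adjusted p = 8.60e-06), with Gstm2 (-1.72 ± 0.16) down. Of cell cycle genes, 3 of 25 measured members rose, 0 fell and 22 did not pass (5 and 0 adjusted over the list alone, adjusted p = 0.00723), with Birc5 (0.79 ± 0.21, n = 2 and 3) and Cdk1 (0.51 ± 0.15) not called with weights, after scale normalization, or without untreated replicate 1 or treated replicate 2. Birc5 was also lost without untreated replicate 2 or treated replicate 3, and Cdk1 without untreated replicate 3. Amino acid, bile acid, fatty acid synthesis, cholesterol, fatty acid oxidation, unfolded protein and interferon genes were shifted down as lists (adjusted p = 1.31e-05 to 0.00781, 3 to 10 members called in each, 4 to 13 adjusted over the list alone). The hepatocyte and P450 lists also passed with an estimated correlation (adjusted p = 0.0342), and the other 11 had adjusted p = 0.0514 to 0.499. Mpeg1 of Kupffer cells (-1.52 ± 0.23) and Krt23 of bile duct cells (-1.02 ± 0.14) fell too. limma called 1271 probes, 577 up and 694 down, 1634 (862 and 772) with dye profiles removed (1198 shared), 1734 (543 and 1191) with the sign turned, 827 after scale normalization and 50 in a fit of only the compared groups. With weights 264 (95 and 169) passed. Simulations of unchanged probes with independent errors gave a median of 13.5 calls without weights and 0 in every one with them. The count was 2005 without treated replicate 3 (1201 up and 804 down) and 1690 (916 and 774) without set B, so the balance turned, as without untreated replicate 2. This left in treated replicate 2 with 1 array in that set.

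In KO, the early times asked whether cells with the deletion responded to HGF. Met was 0.08 ± 0.17 at 0.5 h and -0.11 ± 0.17 at 2 h from untreated. At 0.5 h 1700001D01Rik fell (-1.90 ± 0.26, n = 2 and 2) and was the 1 call of limma, with 646 probes at an unadjusted p under 0.05. At 2 h Lamc3, a laminin chain, rose by 1.08 ± 0.16 (n = 2 and 2), and Serpinb7 (-1.07 ± 0.19, n = 2 and 3) and 1700001D01Rik (-2.49 ± 0.26, n = 2 and 2) fell. Leaving out untreated replicate 1 or 2 or treated replicate 2 ended the calls of Lamc3 and Serpinb7, and leaving out treated replicate 1 that of Lamc3. Scale normalization and leaving out untreated replicate 1 ended the call at 0.5 h. On the Cy3 arrays alone 1700001D01Rik was 0.92 and 0.17 at these times. Interferon response genes were shifted down at 0.5 h (0 up and 0 down of 29, 0 and 0 adjusted over the list alone, adjusted p = 4.44e-06) and up at 2 h (0 up and 0 down of 29, 0 and 0 adjusted over the list alone, adjusted p = 1.82e-10) as a list. The chemokine and NF-kB list was shifted up at 2 h (0 up and 0 down of 18, 0 and 0 adjusted over the list alone, adjusted p = 0.0115), with the chemokine Ccl4 at 1.18 ± 0.42 without a call. The ribosome biogenesis, cytoskeleton, amino acid and glutathione lists were shifted down (adjusted p = 0.00168 to 0.00325, 0 members called in each, 0 to 4 adjusted over the list alone). Under an estimated correlation the interferon list had adjusted p = 0.939 at 0.5 h and the 6 lists at 2 h adjusted p = 0.655 to 0.832. limma made 5 calls at 2 h, 1 up and 4 down, 25 (8 and 17) with weights, 4 (1 and 3) with the sign turned, 48 (25 up and 23 down) after scale normalization and 472 without sets A and B. A fit of only the compared groups gave 0 at both times (1140 and 1616 probes at an unadjusted p under 0.05). At 0.5 h 4 were called with weights, 2 with dye profiles removed and 1 with the sign turned. The count was 0 without treated replicate 1 or treated replicate 3, 2 without untreated replicate 3 at 0.5 h, and at 2 h it was 1 without untreated replicate 2, 2 without untreated replicate 1 or treated replicate 1 or treated replicate 2 and 46 without untreated replicate 3.

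At 12 h in KO, Met was 0.22 ± 0.19 (n = 2 and 3) from untreated. Cps1, the entry enzyme of the urea cycle, fell 2.60-fold (-1.38 ± 0.23, adjusted p = 0.0120), and Isg15 (-1.40 ± 0.25) and the interferon-induced GTPase Igtp (-1.43 ± 0.25) fell. S100a6 rose 2.19-fold (1.13 ± 0.23), and Lgals3, a galactose-binding lectin, rose too (0.88 ± 0.16). Of interferon response genes, 0 of 29 measured members rose, 4 fell and 25 did not pass (0 and 17 adjusted over the list alone, adjusted p = 7.30e-18). Called members included Ifih1 (-1.06 ± 0.21). Of amino acid genes, 0 of 18 measured members rose, 2 fell and 16 did not pass (0 and 9 adjusted over the list alone, adjusted p = 1.27e-11), with Ass1 at -0.67 ± 0.14. Of cytoskeleton genes, 2 of 41 measured members rose, 0 fell and 39 did not pass (3 and 0 adjusted over the list alone, adjusted p = 2.16e-04). Hepatocyte, P450, bile acid, acute phase and chemokine genes were shifted down as lists (adjusted p = 1.78e-08 to 0.00664, 0 members called in each, 1 to 10 adjusted over the list alone), with Cyp2e1 at -1.13 ± 0.24 without a call (adjusted p = 0.0510), and heat shock genes were shifted up (adjusted p = 0.0120, 0 members called). The liver endothelial list was shifted down (0 up and 0 down of 10, 0 and 0 adjusted over the list alone, adjusted p = 0.0317), with Dnase1l3 at -0.68 ± 0.23 without a call. The amino acid list also passed with an estimated correlation (adjusted p = 0.00901), and the other 9 had adjusted p = 0.0998 to 0.456. limma called 19 probes, 3 up and 16 down, 184 (28 and 156) with weights, 63 with dye profiles removed, 206 (19 and 187) after scale normalization and 9 (1 and 8) with the sign turned. Leaving out untreated replicate 1 or treated replicate 2 ended the call of every called gene named here, those of S100a6 and Ass1 were lost without any 1 replicate, and Isg15, Igtp and Ifih1 also without untreated replicate 3. The turned sign ended the calls of S100a6, Isg15, Ifih1 and Ass1, and scale normalization that of S100a6. The count was 1 without untreated replicate 1, 5 without untreated replicate 3 or treated replicate 2, 12 without untreated replicate 2 and 89 within array set C.

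At 24 h in KO, Met was 0.01 ± 0.17 from untreated. Cyp2e1 fell 4.63-fold (-2.21 ± 0.24, adjusted p = 1.58e-05), Gnmt 4.33-fold (-2.12 ± 0.30, n = 3 and 2) and Isg15 3.51-fold (-1.81 ± 0.25). Tuba1a rose 3.15-fold (1.65 ± 0.30, n = 3 and 2), a call lost without untreated replicate 2, and S100a6 2.82-fold (1.497 ± 0.23). Of hepatocyte genes, 0 of 38 measured members rose, 13 fell and 25 did not pass (1 and 18 adjusted over the list alone, adjusted p = 2.40e-11). Of amino acid genes, 0 of 18 measured members rose, 7 fell and 11 did not pass (0 and 10 adjusted over the list alone, adjusted p = 1.10e-09). Among P450 genes, 2 of 33 measured members rose, 9 fell and 22 did not pass (3 and 17 adjusted over the list alone, adjusted p = 8.95e-07). Of cholesterol synthesis and uptake genes, 0 of 16 measured members rose, 3 fell and 13 did not pass (0 and 6 adjusted over the list alone, adjusted p = 2.47e-04). Bile acid, fatty acid synthesis, acute phase and interferon genes were shifted down as lists (adjusted p = 1.86e-07 to 0.0238, 3 to 5 members called in each, 7 to 8 adjusted over the list alone). Kupffer cell markers were shifted down (0 up and 1 down of 11, 0 and 1 adjusted over the list alone, adjusted p = 0.0240), with Marco at -0.59 ± 0.15, and Col3a1 of stellate cells fell (-1.07 ± 0.14). Weights, scale normalization, the turned sign and leaving out any 1 replicate but treated replicate 3 ended the call of Marco. The amino acid list also passed with an estimated correlation (adjusted p = 0.0225), and the other 8 had adjusted p = 0.135 to 0.520. limma called 507 probes, 78 up and 429 down, 307 (37 and 270) with weights, 687 with dye profiles removed (445 shared) and 502 (82 and 420) with the sign turned. With only the compared groups in the fit limma called 0 (1514 probes at an unadjusted p under 0.05), so the calls rest on the spread of all groups. Simulations of unchanged probes with independent errors gave a median of 24 without weights. The count was 160 without untreated replicate 1, 173 without untreated replicate 2, 981 without treated replicate 3, and 1152 within array set C.

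**Figure D2:**
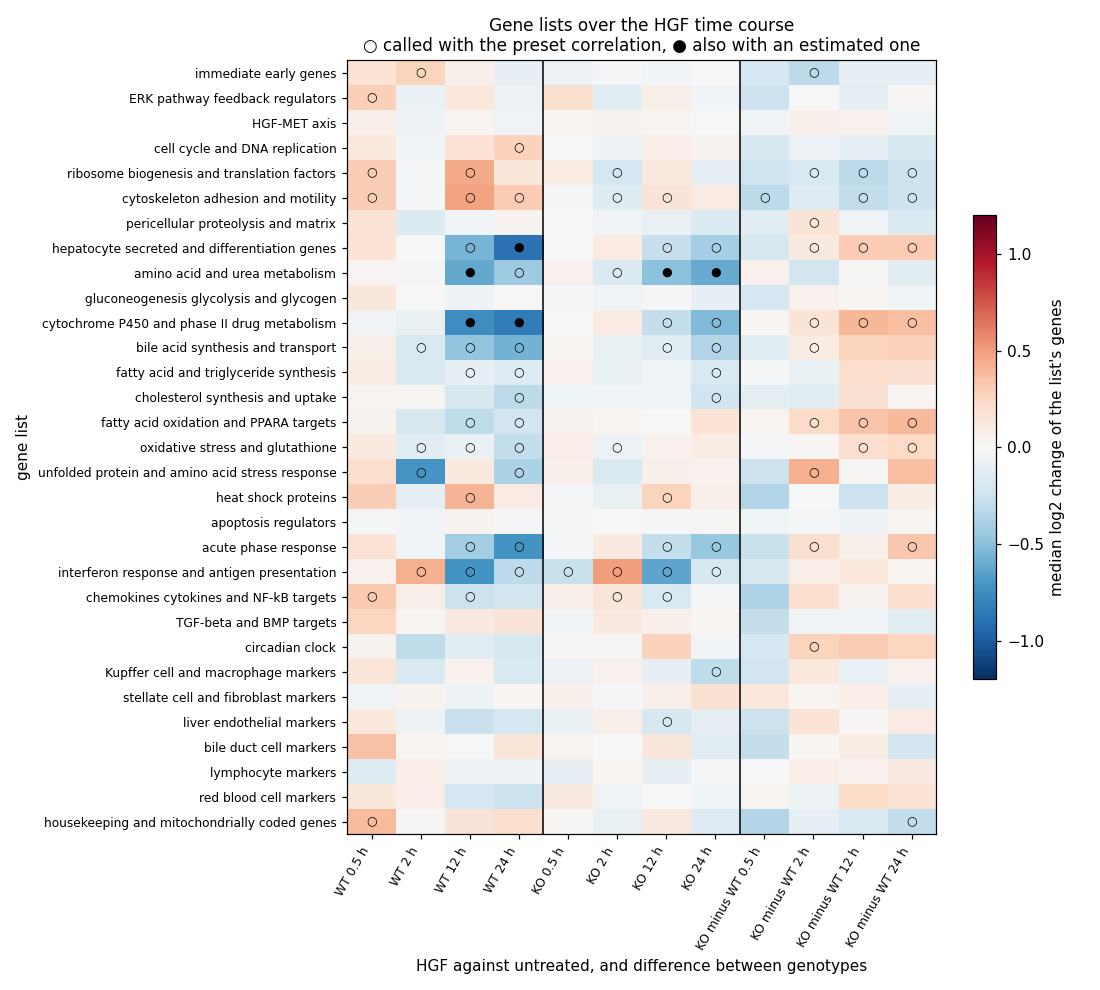
Median log2 difference of the measured members of each of the 31 gene lists (rows) in the HGF comparisons within WT, within KO and in their difference (columns), as a colour scale, with open circles for lists that passed camera and filled circles for those that also passed with an estimated correlation. The filled circles lie at 12 and 24 h in the WT and KO comparisons and at none of the differences.

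The difference of the HGF response, KO minus WT, tested directly which responses depended on the genotype. Met differed in its response by 0.02, 0.17, -0.01 and 0.33 at 0.5, 2, 12 and 24 h. At 24 h Adh1 (2.86 ± 0.37), Cyp2a5 (2.64 ± 0.37), Gstm2 (2.05 ± 0.23) and Gsta3 (2.005 ± 0.16, adjusted p = 9.35e-08) had a higher response in KO than in WT, and all 4 differences also passed with weights. S100a6 (-1.95 ± 0.32) and Tuba1a (-1.88 ± 0.40), which rose in both genotypes, rose less in KO, but weighting and scale normalization ended both calls. That of Tuba1a was also lost with array set as a term, with the sign turned, and without sets A and B, WT 0 h replicate 3, WT 24 h replicate 2, KO 0 h replicate 3 or KO 24 h replicate 2. In the glutathione list, 7 of 39 measured members were higher, 0 lower and 32 did not pass (14 and 2 adjusted over the list alone, adjusted p = 6.01e-07) in the difference. In the P450 list, 4 of 33 measured members were higher, 0 lower and 29 did not pass (7 and 0 adjusted over the list alone, adjusted p = 1.05e-04). Of cytoskeleton genes, 0 of 41 measured members were higher, 6 lower and 35 did not pass (0 and 9 adjusted over the list alone, adjusted p = 1.90e-05). Hepatocyte, fatty acid oxidation and acute phase genes were shifted up (adjusted p = 1.05e-04 to 0.0145, 0 members called in each, 0 to 4 adjusted over the list alone), and ribosome biogenesis and housekeeping genes down (adjusted p = 0.0380, 0 members called in each, 0 to 1 adjusted over the list alone). With an estimated correlation the 8 lists had adjusted p = 0.444 to 0.895. limma called 106 probes at 24 h, 46 up and 60 down, 11 (5 and 6) with weights and 186 with dye profiles removed (100 shared). Simulations of unchanged probes gave a median of 14.5 without weights and 0 in every one with them. The turned sign gave 127 (90 and 37), scale normalization 47 and a fit of only the compared groups 4, among them Gsta3 but not the other 5 genes named here. The count was 67 without KO 0 h replicate 1 and 301 without WT 24 h replicate 3.

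At 12 h the response of Adh1 (1.92 ± 0.37) and Gsta3 (0.91 ± 0.16) was higher in KO, and that of the chloride channel protein Clic1 (-1.39 ± 0.27) and of Itga3 (-0.83 ± 0.16) lower. Scale normalization ended these 4 calls, as did leaving out WT 0 h replicate 3, any 12 h replicate of WT, KO 0 h replicate 1 or 2, or KO 12 h replicate 1. The turned sign ended those of Adh1, Clic1 and Itga3, and leaving out sets A and B those of Adh1, Gsta3 and Itga3. Each of the 4 was also lost without at least 1 other replicate. Of P450 genes, 1 of 33 measured members were higher, 0 lower and 32 did not pass (5 and 0 adjusted over the list alone, adjusted p = 7.47e-09) in the difference, and of glutathione genes, 1 of 39 measured members were higher, 0 lower and 38 did not pass (4 and 0 adjusted over the list alone, adjusted p = 1.11e-05). Cytoskeleton and ribosome biogenesis genes were shifted down (adjusted p = 1.11e-05 to 0.00551, 0 to 1 members called in each, 0 to 3 adjusted over the list alone), and hepatocyte and fatty acid oxidation genes up (adjusted p = 3.30e-05 to 7.82e-05, 0 members called in each, 0 adjusted over the list alone). The 6 lists had adjusted p = 0.314 to 0.782 with an estimated correlation. limma called 11 probes at 12 h, 2 up and 9 down, 14 (4 and 10) with weights, 39 with dye profiles removed, 6 (2 and 4) with the sign turned, 38 (1 and 37) after scale normalization and 1 in a fit of only the compared groups, which kept none of the 4 genes named here. The count was 4 without KO 0 h replicate 1 or WT 0 h replicate 3 or WT 12 h replicate 2, 5 without WT 12 h replicate 3 and 6 without KO 0 h replicate 2 or KO 0 h replicate 3.

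At 2 h Capn11 (3.47 ± 0.47, adjusted p = 0.00127) and Cyp2a4 (3.46 ± 0.49) had a higher response in KO than in WT, where they fell, while that of Prelid2 was lower (-1.997 ± 0.35), a call that the turned sign ended, as did leaving out any 2 h replicate of WT, WT 0 h replicate 2, KO 0 h replicate 1 or 2, or KO 2 h replicate 2 or 3. Fatty acid oxidation, P450, bile acid, hepatocyte, acute phase, unfolded protein, pericellular proteolysis and circadian genes were shifted up as lists (adjusted p = 0.00695 to 0.0443, 0 to 1 members called in each, 0 to 4 adjusted over the list alone), and immediate early and ribosome biogenesis genes down (adjusted p = 0.00695 for both, 0 members called). Under an estimated correlation these lists had adjusted p = 0.637 to 0.673. At 0.5 h cytoskeleton genes were shifted down (0 up and 0 down of 41, 0 and 1 adjusted over the list alone, adjusted p = 0.00667, adjusted p = 0.866 with an estimated correlation), with Tuba1a at -1.86 ± 0.40, and the 1 probe called had no single gene symbol. At 2 h limma called 4 probes (2 up and 2 down), 7 with weights, 15 (9 and 6) with the sign turned, 6 (2 and 4) with no centring and 119 (86 and 33) after scale normalization, and a fit of only the compared groups kept Capn11 and Cyp2a4 alone. The count was 7 without KO 2 h replicate 1 or WT 0 h replicate 3 and 10 without WT 0 h replicate 1. At 0.5 h the count of 1 was 0 with weights, with only the compared groups, with dye profiles removed and with the sign turned, with 1278 probes at an unadjusted p under 0.05, 4 (0 up and 4 down) after scale normalization, and 0 without KO 0.5 h replicate 1 or KO 0.5 h replicate 2 or KO 0.5 h replicate 3 or KO 0 h replicate 2 or WT 0 h replicate 1, 3 without WT 0.5 h replicate 1 and 144 without WT 0 h replicate 2. Over all 4 times together 230 probes were called, 163 with weights (144 shared), 337 with dye profiles removed (194 shared), 252 with the sign turned and 124 without KO 0.5 h replicate 2, 134 without WT 0.5 h replicate 3, 141 without WT 0.5 h replicate 2, 149 without KO 0.5 h replicate 1, 437 without WT 24 h replicate 3 and 442 without WT 0 h replicate 2.

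The genotypes' responses were compared, but not with the turned sign, which moved WT counts. At 24 h 32 probes rose in both and 165 fell in both, against 3.09 and 20.4 for independent responses. Fisher's exact p was 8.04e-25 and 2.6e-109 across probes, which are not independent. Another 6 were called in opposite directions. Of the 18, 65, 847 and 1271 probes called in WT at the 4 times, 61.1, 80, 89.4 and 79.5% had the same sign in KO, and over all probes the responses correlated at r = -0.0142, 0.378, 0.455 and 0.306. Over all 14580 probes the share without overlap ran from 9.60% (KO against WT untreated) to 38.3% (KO against WT at 0.5 h), where chance gives 10%.

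**Figure D3:**
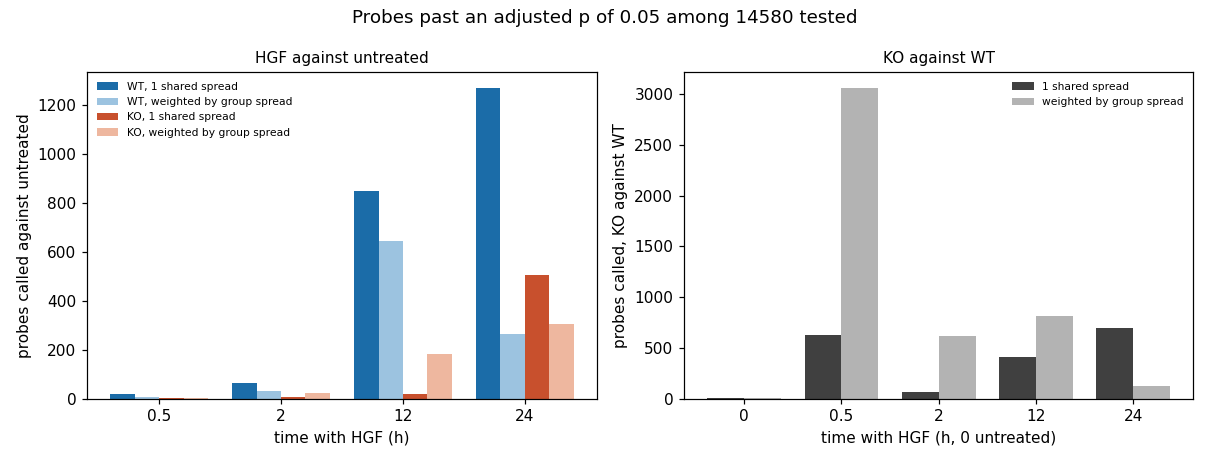
Number of probes called by limma in each comparison (bars), with 1 spread shared by all groups and with replicates weighted by the spread of their group. Weighting raised the counts of KO against WT at 0.5, 2 and 12 h and lowered those at 24 h, from 695 to 127 for the genotypes and from 1271 to 264 for HGF in WT.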

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

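Of the tests in this part, those of dye bias, of the order or run of arrays within array sets C and D, of the scale of the arrays, of the mouse strain, of a difference between array sets C and D and of the direction of 1 array were chosen only after the result was seen.

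The HGF response of KO minus that of WT was tested directly, and the results in this and the next paragraph passed that test by limma or camera. There was 1 such probe at 0.5 h, and 4 at 2 h, 11 at 12 h, 106 at 24 h and 230 at any time. At 2 h the log2 difference was 3.47 for Capn11, 3.46 for Cyp2a4, -1.997 for Prelid2 and -2.87 for 1700001D01Rik. At 12 h it was 1.92 for Adh1, 0.91 for Gsta3, -0.83 for Itga3, -1.39 for Clic1, -1.64 for Apbb2 (-0.7543 by its other probe, not called), -2.53 for 1700001D01Rik and -2.55 for Dyrk1a (0.1272 by its other probe, not called). At 24 h the metabolic genes Adh1 (2.86), Cyp2a4 (2.69), Cyp2a5 (2.64), Gstm2 (2.05), Gsta3 (2.00), Gsta2 (1.61), Gstm6 (1.48), Hgd (1.45, and 0.6544 by its other probe, not called), Ephx1 (1.35) and Acox2 (0.88) had a higher response in KO, as had the keratin Krt23 (0.93). Lower at 24 h were the responses of the structural genes Itga3 (-0.89), Krt7 (-0.97), Krt8 (-1.16), Tuba1a (-1.88) and Tubb6 (-2.31), and those of S100a6 (-1.95), Abcg8 (-1.04), Dennd1c (-2.39), 1700001D01Rik (-2.75) and Enpp3 (-3.47). At 2 h the call of Prelid2 was lost with the turned sign and without any WT 2 h replicate. At 12 h those of Adh1, Gsta3, Itga3, Clic1 and Dyrk1a were lost with scale normalization and without WT 0 h replicate 3, any WT 12 h replicate or KO 0 h replicate 1 or 2, and that of Apbb2 with the turned sign. At 24 h those of Adh1, Cyp2a5, Gstm2, Gsta3 and 1700001D01Rik held with weights, scale normalization, array set as a term, the turned sign and without sets A and B. That of Enpp3 was lost with the turned sign, and each of the other 24 h calls named here with weights. Leaving out WT 24 h replicate 2 also ended those of Tubb6, Tuba1a, Abcg8, Acox2 and Krt23, each of which was lost without at least 1 other replicate too. A fit of only the compared groups kept Capn11 and Cyp2a4 at 2 h, Apbb2 at 12 h and Gsta3 and Gsta2 at 24 h, and none of the others named here. On the Cy3 arrays alone 1700001D01Rik was not called and turned to 0.51 in the difference at 12 h, and it was not called on the Cy5 arrays alone either.

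Among gene lists, the cytoskeleton list differed at 0.5 h (adjusted p = 0.00667), 12 h (1.11e-05) and 24 h (1.90e-05), ribosome biogenesis at 2 h (0.00695), 12 h (0.00551) and 24 h (0.038), and hepatocyte genes at 2 h (0.0443), 12 h (3.30e-05) and 24 h (0.000105). P450 genes differed at 2 h (0.0223), 12 h (7.47e-09) and 24 h (0.000105), fatty acid oxidation at 2 h (0.0142), 12 h (7.82e-05) and 24 h (0.000127), glutathione genes at 12 h (1.11e-05) and 24 h (6.01e-07), and acute phase genes at 2 h (0.00695) and 24 h (0.0145). At 2 h immediate early and unfolded protein genes (0.00695 each), pericellular proteolysis and circadian genes (0.0443 each) and bile acid genes (0.0406) also differed, and at 24 h housekeeping genes (0.038). None of these list differences passed with an estimated correlation.

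Splits of the same replicates into groups of these sizes were counted, and numbers of splits as large include the real one. For 3 replicates against 3, the 10 splits cannot give a share under 0.05. For KO against WT the real count and the highest of the others were 9 and 2 untreated, 627 and 0 at 0.5 h, 63 and 1 at 2 h, 414 and 43 at 12 h, and 695 and 1607 at 24 h, where 2 splits were as large. The split with 1607 calls puts the array set B replicates of both genotypes together with KO 24 h replicate 1, and with array set as a term the real count was 1278. For HGF in WT the counts were 18 and 37 at 0.5 h (4 splits as large), 65 and 1 at 2 h, 847 and 1 at 12 h, and 1271 and 1931 at 24 h (2 splits as large). The split with 1931 puts the set B replicates of untreated and 24 h WT together, and the count with array set as a term was 1979. For HGF in KO they were 1 and 1, 5 and 9, 19 and 2, and 507 and 3 at the 4 times. For the differences 100 splits were drawn. Splits as large were 13 at 0.5 h (1 call, highest other 807) and 7 at 24 h (106 and 2005). There were 3 at 2 h (4 and 12), 2 at 12 h (11 and 18) and 2 at any time (230 and 1143). The latter shares are under 0.05, but other splits called more, so chance stays open. Averaged over time the genotype difference had 1 (1488 and 87), but chance stays open if times share mice. Splits calling several times the real number point to a sample structure including the array sets.

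More probes differed between KO and WT at 0.5 h (627) than untreated (9). Smaller spread at 0.5 h is argued against by the root mean square difference after subtraction of the error variance, 0.3205 (0.296 to 0.339 leaving out 1 replicate) against -0.0984 (-0.162 to 0.125) untreated. The scatter of untreated replicates over array sets is argued against by the lowest count with 2 replicates per group, 270 at 0.5 h against 73 untreated, and dye bias as the whole cause by the 384 calls at 0.5 h with dye profiles removed, against 18. The order of the arrays within set D cannot be told apart from the genotype, since 0 arrays of one genotype were numbered among those of the other. An early effect of the missing receptor stays open beside array order, strain and partial dye bias.

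Probes that responded at 12 h moved less in KO than in WT, 81.9% of 977 being smaller. The ratio of mean responses was 0.641 (0.505 to 0.781 leaving out 1 replicate). Array sets are argued against by 0.6344 without sets A and B, and the doubted replicates by 0.6919 without both (77.0% smaller). No ratio was taken with the turned sign. Array scale cannot be told apart from the effect, since after scale normalization the ratio was 0.9786 (0.712 to 1.157, 54.9% smaller). Then 222 probes in WT and 206 in KO were called, against 847 and 19. Array order in set C and strain cannot be told apart from genotype, as 0 arrays of one genotype were numbered among the other's and 0 strain labels were shared. At 24 h the ratio was 0.772 (0.593 to 1.105), the doubted replicates are argued against (0.7397 without both, at most 0.985), and array sets cannot be told apart from the effect (0.8942 without sets A and B, up to 2.319), nor can the scale (0.8443, up to 1.173). A weaker HGF response without Met was not separated from these and stays open.

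Without array sets A and B, 1568 probes in WT and 472 in KO responded at 2 h, against 65 and 5 with all replicates. A difference between sets C and D as a whole is argued against by the highest count at 0.5 h there, 3. With array set as a term the 2 h counts with all replicates were 1 and 2 with 0 shared, which goes with such a difference, but sets C and D are then linked only through 1 untreated and 1 treated KO replicate in set A. The direction of the Cy5 array of WT 0 h replicate 3 is argued against in KO, where it does not enter the comparison, by the 472 calls. In WT it goes with the rise, with 1098 calls when that sign was turned, but a poor array would also give the 437 found without that replicate. The run of the 2 h arrays within set D cannot be told apart from time, since 0 arrays of one time were numbered among those of the other. A response to HGF at 2 h may be an explanation, and no test separated it from that run. Without these sets 1690 and 1152 probes responded at 24 h, so the counts did not peak at 2 h.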

How the results depend on the processing

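The removal of dye profiles, the turned sign, leaving out both doubted replicates and the weighting by group were chosen only after the data were seen. The other alternatives were planned. Counts of called probes are given where they moved over 1.5 times, in the order of the times, with the value with all choices as reported in the report. Where a count rose or fell, the cause was not tested unless fewer samples or probes are part of the alternative. Without centring no count moved by over 1.5 times.

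Scale normalization gave for KO against WT 15 untreated, 1046 at 2 h, 234 at 12 h and 398 at 24 h. HGF in WT gave 152, 1343, 222 and 827, HGF in KO 0, 48 and 206 at 0.5, 2 and 12 h, and the differences 4, 119, 38 and 47, with 488 at any time. The list interferon response and antigen presentation in KO against WT at 12 h, not called as reported, turned (adjusted p = 0.00867). The list interferon response and antigen presentation in difference of HGF response KO minus WT at 12 h turned too (adjusted p = 0.00807).

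With 1 dye orientation enough, untreated KO against WT gave 4 calls, HGF in KO 2, 1 and 9 at 0.5, 2 and 12 h, and the difference at 0.5 h 3. There 1700001D01Rik turned to 0.0805 in KO at 0.5 h. With only probes without a missing value, fewer probes were tested, and the counts were 5 untreated and 345 at 0.5 h for KO against WT, 11 for HGF 0.5 h in WT, and 0 for 0.5 h and 0 for 2 h in KO. With no probe filter they were 5 for untreated KO against WT, 4 at 0.5 h and 37 at 12 h in KO, and 2 for the difference at 0.5 h. With 60 single arrays and a dye term, untreated KO against WT gave 23, 2 h 154, HGF 2 h in WT 210, HGF in KO 4, 11 and 131 at 0.5, 2 and 12 h, and the differences 0, 10, 48 and 206, with 383 at any time.

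With only the compared groups in the fit, the spread came from 6 or 12 replicates. KO against WT then gave 0 untreated, 2256 at 0.5 h, 402 at 2 h and 10 at 24 h. HGF in WT gave 0, 1, 88 and 50, HGF in KO 0, 0 and 0 at 0.5, 2 and 24 h, and the differences 0, 2, 1 and 4.

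Weighting replicates by the spread of their group gave 2, 3064, 615, 813 and 127 for KO against WT. HGF in WT gave 7, 32 and 264 at 0.5, 2 and 24 h, HGF in KO 4, 25, 184 and 307, and the differences 0, 7 and 11 at 0.5, 2 and 24 h. Here the spread differed between groups (residual SD 0.165 to 0.431), so weighting raised counts between groups of small spread and lowered those at 24 h.

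Array set as a term gave 39, 1485, 145, 802 and 1278 for KO against WT. HGF in WT gave 2, 1 and 1979 at 0.5, 2 and 24 h, HGF in KO 8, 2, 50 and 879, the differences 13 at 2 h and 224 at 24 h, with 538 at any time, and the averaged genotype difference 2233. In WT at 2 h Ndrg1 turned to -0.29, Jun to -0.22 and Baat to 0.17, and the amino acid list turned with an adjusted p = 0.0284. Leaving out array sets A and B gave 73, 1652, 192, 948 and 1562 for KO against WT, 3 and 1568 for HGF at 0.5 and 2 h in WT, 2, 472, 89 and 1152 in KO, 0, 19, 20 and 235 for the differences, 613 at any time and 2631 averaged. The unfolded protein list then turned in WT at 0.5 h (adjusted p = 0.0117) and in the difference at 12 h (adjusted p = 0.0218).

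Only the Cy3 arrays, 30 of 60, gave 3, 1741, 34, 106 and 231 for KO against WT. HGF in WT gave 31 at 0.5 h and 640 at 24 h, HGF in KO 0, 2, 0 and 219, the differences 2 at 12 h and 22 at 24 h, and the averaged difference 718. On these arrays the difference of 1700001D01Rik in KO against WT untreated turned to -0.072, and its change to 0.92, 0.17, 0.21 and 0.0298 at the HGF times in KO, and to 0.51 in the difference at 12 h. The glutathione list turned in untreated KO against WT (adjusted p = 0.878) and in KO at 2 h (0.898), and the cell cycle list in KO against WT at 24 h (0.931).

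Only the Cy5 arrays gave 58, 5, 211 and 407 for KO against WT at the 4 HGF times. HGF 0.5 h in WT gave 3, HGF in KO 0, 0 and 136 at 0.5, 2 and 24 h, the differences 0 and 36 at 0.5 and 12 h with 100 at any time, and the averaged difference 766. Turned on these arrays were Ighv6-6 in KO against WT (-0.50) and in WT (0.0207) at 12 h, Pex11a (0.0373), Ccl5 (0.0247) and Dbp (0.12) in KO against WT at 0.5 h, and averaged Mx1 (0.0916). In WT at 12 h Mmp14 (0.0350), Slc2a2 (0.0107), Mttp (0.18), Dgat1 (0.0327) and Insig2 (0.0207) turned. Among lists, gluconeogenesis turned in KO against WT at 0.5 h (adjusted p = 0.0116), and in the difference at 2 h hepatocyte (0.677) and P450 genes (0.963). The list interferon response and antigen presentation in difference of HGF response KO minus WT at 2 h turned to a call (4.90e-05).

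Removal of the dye profiles gave 18, 384, 167 and 628 for KO against WT up to 12 h, 8, 245 and 1486 for HGF in WT up to 12 h, 2 and 63 in KO at 0.5 and 12 h, and 0, 7, 39 and 186 for the differences. Without both doubted replicates the counts were 50, 1008 and 118 for KO against WT up to 2 h, 5, 567 and 367 for HGF in WT up to 12 h, 67 at 12 h in KO, and 7 and 5 for the differences at 2 and 12 h. The unfolded protein list turned there in WT at 0.5 h (adjusted p = 0.0335), as did the list unfolded protein and amino acid stress response in difference of HGF response KO minus WT at 12 h (0.000779). The turned sign of the Cy5 array of WT 0 h replicate 3 gave 3 and 1098 for HGF at 0.5 and 2 h in WT, 9 at 12 h in KO, and 0, 15 and 6 for the differences up to 12 h.

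With replicate numbers as a fixed block, the counts of HGF in KO were 0 at 0.5 h and 31 at 12 h, and no other count moved by over 1.5 times.

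Leaving out 1 replicate gave for KO against WT 2 to 45 untreated, 151 to 373 at 0.5 h, 25 to 43 at 2 h, 213 to 322 at 12 h and 539 to 1344 at 24 h. HGF in WT gave 5 to 652, 20 to 437, 318 to 1207 and 927 to 2005, and HGF in KO 0 to 2, 1 to 46, 1 to 24 and 160 to 981. The differences gave 0 to 144, 3 to 10, 4 to 15 and 67 to 301, with 124 to 442 at any time, and the averaged difference 1229 to 2074. The unfolded protein list in the difference at 12 h had an adjusted p of 0.00160 (turned, without WT 0 h replicate 3) to 0.983. Of the named gene calls refitted without a replicate of their groups, 4323 kept direction and threshold and 771 did not pass. A group left with 2 replicates has the fit's pooled spread.

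Of the 131 list calls, 10 remained calls with an estimated correlation, and the other alternatives gave 108 to 153 list calls. Of 513 named gene calls, 507 kept direction and threshold without centring, 496 with dye profiles removed, 490 with single arrays, 457 with array set as a term, 456 with the turned sign, 393 with weights, 385 with scale normalization, 278 on Cy5 arrays alone and 251 on Cy3 arrays alone. A fit of only the compared groups, which has no averaged comparison, kept 160 and lost 277. Signal over background per array was not analysed here, so what low signal limits is unknown.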

Other observations

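The values in this part were chosen for description after they were seen, and are given without an explanation. Aldh1a1 rose in KO between untreated and 24 h (1.59 ± 0.24) and was 1.74, 2.55 and 2.62 higher in KO than in WT at 0.5, 12 and 24 h, with 0.98 at 2 h not called. Scale normalization ended the call of its rise in KO.

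Probes of 1 gene did not always move together. In untreated KO against WT the called probe of Furin was -0.83 and its other probe 0.03, and those of Loxl2 were 0.85 and 0.39. Replicates of untreated WT correlated across probes at r = -0.209 to 0.391, and those of WT 0.5 h at 0.750 to 0.809. Replicates of array set B from different groups correlated across probes at 0.377, 0.366 and 0.399, with no group means removed.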
